A study of Homo sapiens with 12 samples.

How the data were processed

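RNA sequencing libraries of 2 liver cancer cell lines were used, 3 libraries for each of 4 groups: Huh6 and Huh7 control cultures and Huh6 and Huh7 cultures with STRAP targeted. Groups were taken from the labels, and replicates were numbered in accession order, so a number names a library and pairs nothing. Per the labels' protocols, cells received CRISPR/Cas9 plasmids with a green fluorescent protein construct and were sorted as single cells, Huh7 cells partly in conditioned medium. RNA was enriched with oligo-dT beads and copied from random hexamers, per the labels' protocols, and no strand marking is stated there. No sequencing batch or date is given in the labels.

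The authors deposited 1 table of CPM for 41718 Ensembl genes, which are counts scaled to the same total in each library. Per the submitters' processing notes, the tools used were Trimmomatic 0.33, STAR 2.4.2a and DESeq2 1.16.1 with the genome build hg38, and the role of each is not stated. The read counter and the annotation are not given in the sources used here. Each deposited CPM column was matched to a sample by its name, and 0 columns of values were left unmatched. The table gives 14275 genes without a symbol, which were counted but not named, 787 without a biotype, 18152 protein-coding genes and 0 rows without a gene identifier. No library pair was identical. Positions are those of the table, and of 40931 identifiers with a position, 40617 were found in GENCODE release 29, 96.1% of them with the same start and end.

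The low CPM values of a library are whole multiples of what 1 count is worth, and dividing by that step gave totals of 74859310 to 113643089 counts. At least 99.83% of the values of each library lay within 0.1 of a whole count, and so did 100% of the low values. In 3 libraries the step lies close to 0.01 CPM, so rounding of the table to that step was tested and at most 0.02% of their low values were multiples of 0.01. The totals are counts and not distinct reads: SMN2 stood at 99 to 100.2% of the value of its near-identical copy SMN1, and the pseudogenes EEF1A1P5 and EEF1A1P6 at 76.4 to 78.4% and 68.2 to 70.3% of EEF1A1, values that reads counted at more than one locus would give. Pseudogenes held 12.29 to 14.64% of the CPM. Genes found to share reads with such copies, or to overlap an antisense gene, are therefore reported as uncertain. Copies were compared for SMN1, EEF1A1, FABP5 and CES1 alone, so other named genes were not checked for them. SMN1 and SMN2 are still counted as separate members of the SMN list.

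The main test was limma 3.58.1 in R 4.3.3 with a trended prior on log2(CPM + 1), with the 12 libraries in 1 fit of 4 group means and no covariate, for genes with at least 1 CPM in at least 3 libraries. The contrasts were the change in each line, their average, their difference (Huh6 minus Huh7) and the difference between the control groups. P-values were two-sided and adjusted by Benjamini-Hochberg over the 18396 genes of each contrast, with a threshold of 0.05. STRAP was also tested with an exact permutation test. Because the unit is CPM, the count tools edgeR 4.0.16 and DESeq2 1.42.0 were run as alternatives on the recovered counts.

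For 24 gene lists with 484 entries, camera tested each list against the other genes with the inter-gene correlation preset at 0.01, adjusted over the 24 lists of a contrast. The same test with an estimated correlation and the fry test were alternatives. The lists cover Wnt feedback and pan-tissue targets, Wnt-dependent perivenous liver genes, Wnt pathway components, SMN complex and Sm proteins, TGF-β receptors and SMADs, TGF-β target genes, proliferation, hepatocyte function, fetal liver and progenitor genes, epithelial and mesenchymal genes, p53 targets, cholesterol and fatty acid synthesis, unfolded protein and amino acid stress, the interferon response, hypoxia and glycolysis, ribosome biogenesis, YAP targets, NF-kB and inflammatory genes, and markers of stromal, endothelial, leukocyte and cholangiocyte cells. The groups, tests, lists and alternatives, and the rule for named genes, were fixed before the data were examined.

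Named genes were STRAP, CTNNB1, AXIN2, LGR5, MYC and CCND1 whatever their p-value, and others by rule. In each line these were the 12 largest rises and 12 largest falls past the threshold whose groups did not overlap and whose higher mean reached 5 CPM. To them were added the 10 largest shared rises and falls, 8 per direction for the difference between lines and for the controls, and up to 4 members of each list with the smallest adjusted p. Not each of these is printed, 2 that the rule names are counted but not reported here, and the examples given for a list were mostly those that kept their call in the alternatives.

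The procedure was tested on simulated counts drawn from the real control means, library sizes and dispersions, with 200 genes changed in Huh6 and 0 in Huh7, in 5 draws of 17752 to 17804 genes. For Huh6, 13.6% of genes changed 1.5-fold were recovered, 55.2% of those changed 2-fold, 94% at 4-fold and 97.6% at 8-fold. Of the simulated Huh6 calls, 7.4 to 18.1% were genes that had not been changed (10 to 29 genes), above the nominal 5%, while in Huh7 0 to 4 genes were called with no change made. Over the 5 draws 2 lists were called in Huh7 with no change, and a list shifted by 0.5 was called in 5 of 5. Genes were drawn independently of each other, so the simulation does not test list calls where members vary together. In the real data the estimated correlation was 0.678 for ribosome biogenesis, 0.462 for proliferation and 0.361 for the SMN list. A first run with a single draw of another seed was replaced by these 5 draws, because 1 draw gave the share of false calls with little precision.

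Alternatives were a pseudocount of 0.1 or 3, no filter on low values or a minimum of 5 CPM, scaling by median-of-ratios size factors or quantile normalization, each line fitted alone, limma's array weights, a robust prior, the count tools, a 2-fold minimum, and leaving out each of the 12 libraries in turn. After the data had been seen, a fit of protein-coding genes alone with rescaled CPM and a fit with the median shift of each 20 Mb region removed were added. Calls were also counted in other splits of the libraries, 10 for 3 against 3 libraries and 100 drawn for contrasts over both lines. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the table and the plots.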

Results

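Gene expression was measured by RNA sequencing in 2 human liver cancer cell lines, Huh6, which came from a hepatoblastoma, and Huh7, which came from a hepatocellular carcinoma. In each line, cultures in which the gene STRAP had been targeted with CRISPR/Cas9 plasmids were compared with control cultures. There were 4 groups of 3 libraries, 12 libraries in all. Transfected cells had been sorted as single cells, per the labels' protocols, and the labels do not say whether the libraries of a group came from different clones, so the p-values measure the spread between these libraries. STRAP, the serine/threonine kinase receptor associated protein, binds TGF-β receptors and takes part in the SMN complex, which assembles the small nuclear ribonucleoproteins of the spliceosome. The study addressed whether STRAP acts on Wnt/β-catenin signalling and growth in liver cancer cells.

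The depth of each library was taken as the sum of its gene counts, recovered from the steps of the deposited CPM values, which are counts scaled to the same total in each library. It was 74859310, 96676691 and 80903898 counts in the Huh6 controls and 78656481, 90132290 and 99424782 in the Huh6 knockouts. In Huh7 it was 96386967, 106172451 and 100703370 counts in the controls and 113643089, 111975581 and 99036311 in the knockouts. A gene listed at 0 could be present at up to 0.0264 to 0.0401 CPM, which is 3 counts of a library's total, a limit for counting error alone. Of the 41718 genes listed, 18396 reached 1 CPM in at least 3 libraries and were tested. The translation factor gene EEF1A1 was the most abundant in each Huh6 library, with 0.849 to 1.106% of the total, though its own level is uncertain because pseudogene copies are listed at 68.2 to 78.4% of it, and the fetal liver gene AFP was so in each Huh7 library, with 1.976 to 4.892%. Levels below are mean CPM ± SD (n = 3 libraries per group). Changes are knockout minus control on the log2(CPM + 1) scale, which understates the change of genes with low values, and adjusted p-values come from limma.

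STRAP itself (ENSG00000023734, chromosome 12, 15882391 to 15903478, hg38) was lower in each knockout library than in each control library of its line. In Huh6 it stood at 246.0, 250.8 and 240.2 CPM in the controls and at 86.9, 83.3 and 98.8 CPM in the knockouts. The knockout mean of 89.7 ± 8.13 was 36.5% of the control mean of 246 ± 5.31, a 2.74-fold lower level (log2 change -1.45, SE 0.15, adjusted p = 0.000184). In Huh7 it stood at 196.8, 206.2 and 189.4 CPM in the controls and at 81.2, 127.6 and 125.1 CPM in the knockouts. The knockout mean of 111 ± 26.1 was 56.4% of the control mean of 197 ± 8.45 (log2 change -0.85, SE 0.15, adjusted p = 0.00458). STRAP mRNA was still counted in each of the knockout libraries, and protein was not measured here. A two-sided exact permutation test of 3 against 3 libraries gave p = 0.1 in either line, the smallest value it can give. The change did not pass the test for a difference between the lines (difference -0.60, SE 0.21, adjusted p = 0.101).

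**Figure D1:**
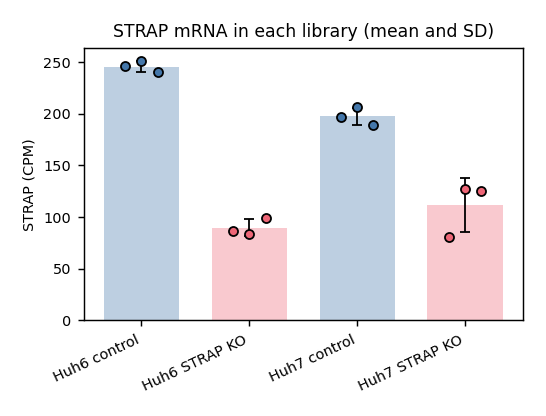
STRAP level in CPM (y axis) in each library, as points, with the mean of the 3 libraries of a group as a bar and the SD as the error bar. The knockout means, 89.7 CPM in Huh6 and 111 CPM in Huh7, lie below the control means of 246 and 197 CPM.

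In Huh6, the largest rise belonged to IGFBP2, which encodes a binding protein of insulin-like growth factors (ENSG00000115457, chromosome 2, 216632828 to 216664436). It went from 2.35 ± 1.12 CPM in the controls to 80.6 ± 42.0 CPM in the STRAP knockouts (log2 change 4.48, SE 0.74, adjusted p = 0.00187). TIMP3, an inhibitor of matrix metalloproteinases (chromosome 22, 32801701 to 32863043), rose from 1.2 ± 0.55 to 30.9 ± 9.92 CPM (log2 change 3.87, SE 0.26, adjusted p = 2.28e-05). The adhesion molecule gene ALCAM rose from 0.625 ± 0.201 to 35.2 ± 31.4 CPM, and the Wnt ligand gene WNT5B from 5.13 ± 1.17 to 71.3 ± 57.0 CPM. The largest falls included OLR1, a receptor for oxidised lipoprotein, from 319 ± 49.7 to 21.8 ± 4.26 CPM (log2 change -3.82, SE 0.20, adjusted p = 7.01e-06), and the cancer/testis gene CT55, from 15.3 ± 0.865 to 0.276 ± 0.125 CPM (log2 change -3.68, adjusted p = 9.12e-09). NAV3, which encodes a neuron navigator protein, fell from 48.7 ± 3.05 to 3.05 ± 3.01 CPM, and NEBL, which encodes the actin-binding protein nebulette, from 40.3 ± 1.53 to 3.17 ± 2.59 CPM. LOXL1, a collagen cross-linking enzyme gene, stood at 1.6 ± 0.488 and 47.3 ± 38.5 CPM, but LOXL1-AS1 lies antisense to it, so the share of each in these counts is uncertain.

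Altogether 3573 genes rose and 1936 fell in Huh6, which is 29.9% of those tested, and 64.9% of the calls were higher. Pseudogenes were 391 of the genes that rose and 520 of those that fell. The share higher was 48.5% after scaling by size factors and 46.0% after quantile normalization. At least a 2-fold change was also reached by 838 of the genes that rose and 239 of those that fell. The 3 knockouts and 3 controls did not overlap for 9062 genes (49.3%), against 10% by chance. Genes matched as histones by symbol made up 0.121 to 0.136% of the counts in the controls and 0.201 to 0.230% in the knockouts. That match also takes in the imprinted RNA H19, which rose in Huh6, so the share is not of histones alone. Mitochondrial genes made up 1.68 to 2.01% in the controls and 2.35 to 2.61% in the knockouts. Without control replicate 1, 2 or 3 the total of 5509 genes became 3631, 3154 or 3311. Of the 12 largest rises 11, and of the 12 largest falls 9, stayed past the threshold in each left-out fit that tested them. CT55 reached 1 CPM in the Huh6 controls alone, so it was not tested when a Huh6 control was left out.

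Among gene lists fixed before the data were examined, 4 were lower in the Huh6 knockouts by camera, a test of a list against the other genes, and 1 was higher. Where a single count is given for a list, adjusting over the list alone gave the same count. The ribosome biogenesis list, factors that make ribosomal subunits, had 9 of 21 members lower and none higher (12 lower adjusted over the list alone; median log2 change -0.44, adjusted p = 1.85e-06). Examples are POLR1A, the largest subunit of RNA polymerase I, at -0.68, UTP20 at -0.87 and the small nucleolar ribonucleoprotein gene NOP56 at -0.81, from 414 ± 23.7 to 237 ± 15.3 CPM. In the proliferation list 7 of 28 members fell and none rose (6 lower adjusted over the list alone; median -0.31, adjusted p = 7.86e-05), among them the mitotic kinase genes CDK1 (-0.78) and AURKA (-0.56) and the replication helicase gene MCM6 (-0.64). The list of SMN complex and Sm proteins, the complex in which STRAP takes part, had 3 of 19 members lower (1 adjusted over the list alone; median -0.23, adjusted p = 0.000642). SNRPF, an Sm protein gene, stood at -0.54 among them, but at 0.03 once the median of its chromosome region was removed. Cholesterol synthesis genes fell in 4 of 22 cases (4 adjusted over the list alone; median -0.20, adjusted p = 0.0229), with the mevalonate kinase gene MVK at -0.58. The call for MVK in Huh6 was lost once the median of its chromosome region was removed (-0.32, adjusted p = 0.059). Wnt pathway components rose in 8 of 30 cases and fell in 2 (8 and 2 adjusted over the list alone; median 0.29, adjusted p = 0.0279), with the receptor gene FZD1 at 1.38, the cofactor gene BCL9 at 1.11, the corepressor gene TLE3 at 1.09 and the signal transducer gene DVL3 at 0.99. None of these 5 calls held with the correlation between genes estimated from the data, where the lowest result was adjusted p = 0.736 with an estimated correlation. The fry test, which takes each list by itself, ended the calls for proliferation in Huh6 (adjusted p = 0.0961) and cholesterol synthesis in Huh6 (0.143). The call for cholesterol synthesis in Huh6 ended without control replicate 3 (adjusted p = 0.0725) and without knockout replicate 3 (adjusted p = 0.169), and that for Wnt pathway components in Huh6 without knockout replicate 2 (adjusted p = 0.0773). Of 15 other alternatives 6 ended the call for cholesterol synthesis in Huh6 and 7 that for Wnt pathway components in Huh6, with adjusted p up to 0.736 for each.

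The other lists were not called in Huh6. TGF-β receptors and SMADs rose in 10 of 20 cases and fell in 1 (10 and 1 adjusted over the list alone; median 0.46, adjusted p = 0.0903), including SMAD3 (0.74) and the SMAD corepressor genes SKIL (0.98) and SKI (0.63). SMAD3 lies in the same raised chromosome region as TLE3. TGF-β target genes rose in 7 of 18 cases and fell in 1 (7 and 2 adjusted over the list alone; median 0.46, adjusted p = 0.279). The list of unfolded protein and amino acid stress genes rose in 6 of 21 cases (5 adjusted over the list alone; adjusted p = 0.257), and the risers CALR (0.94), HSPA5 (0.88) and PDIA4 (0.97) encode chaperones of the endoplasmic reticulum. Hepatocyte function genes rose in 5 of 32 cases and fell in 1 (3 and 0 adjusted over the list alone; adjusted p = 0.693), with the transcription factor gene CEBPA from 178 ± 15.8 to 365 ± 82.7 CPM. In the fetal liver and progenitor list 4 of 17 rose and 3 fell (4 and 4 adjusted over the list alone; adjusted p = 0.85), and the imprinted RNA H19 went from 191 ± 38.0 to 720 ± 254 CPM. The p53 targets had 3 of 22 higher and 2 lower (3 and 1 adjusted over the list alone; median 0.04, mean 0.19, camera pointing down, adjusted p = 0.958), with TP53INP1 at 1.98 and the DNA repair gene XPC at -1.17. Fatty acid synthesis genes fell in 4 of 14 cases (4 adjusted over the list alone; adjusted p = 0.208), with SCD, the stearoyl-CoA desaturase gene, at -0.69. The hypoxia and glycolysis list had 2 of 18 higher and 3 lower, with a median of -0.10, a mean of 0.08 and a camera result pointing down (adjusted p = 0.605).

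For the remaining lists in Huh6, the camera result was adjusted p = 0.641 for Wnt feedback and pan-tissue targets, 0.966 for perivenous liver genes, 0.693 for epithelial genes (median 0.04, mean 0.08, camera pointing down), 0.857 for mesenchymal genes, 0.342 for the interferon response, 0.451 for YAP targets and 0.652 for NF-kB and inflammatory genes. Markers of cell types other than hepatocytes were low or mixed. The endothelial markers ENG and TIE1 rose, ENG from 0.874 ± 0.0978 to 3.98 ± 1.31 CPM, but the list was not called (2 of 3 members, adjusted p = 0.286). The leukocyte list rose in 2 of 7 cases (adjusted p = 0.605), with the invariant chain gene CD74 from 21.9 ± 2.91 to 51.5 ± 22.1 CPM. Stromal markers had 1 of 7 higher and 1 lower (adjusted p = 0.617). Cholangiocyte markers had 1 of 9 higher and 1 lower, with a median of 0.02, a mean of -0.15 and a camera result pointing down (adjusted p = 0.534).

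In Huh7, the largest rise belonged to SI, the sucrase-isomaltase gene of the intestinal brush border (ENSG00000090402, chromosome 3, 164978898 to 165078495), which went from 4.47 ± 1.70 CPM in the controls to 161 ± 128 CPM in the STRAP knockouts (log2 change 4.24, SE 0.77, adjusted p = 0.00517). The glucose transporter gene SLC2A2 rose from 8.99 ± 10 to 117 ± 47.6 CPM (log2 change 3.93, SE 0.63, adjusted p = 0.00315). GUCY2C, the receptor of guanylin peptides in the gut, rose from 13.4 ± 4 to 168 ± 117 CPM, and MYH14, a non-muscle myosin gene, from 5.75 ± 4.86 to 55.1 ± 19.8 CPM. The largest falls included THBS4, a thrombospondin gene, from 25.8 ± 7.49 to 2.24 ± 1.90 CPM (log2 change -3.16, SE 0.34, adjusted p = 0.000684), and GC, the vitamin D binding protein gene, from 80.4 ± 31.6 to 8.07 ± 2.94 CPM (log2 change -3.13, adjusted p = 0.000434). SLC7A1, a transporter of cationic amino acids, fell from 59.4 ± 11.1 to 15.3 ± 8.53 CPM. The carboxylesterase gene CES1 stood at 0.509 ± 0.389 and 12.9 ± 7.34 CPM, with the copy CES1P1 listed at 39.3 to 41.6% of its level, so its own share is uncertain.

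Altogether 2304 genes rose and 1994 fell in Huh7, which is 23.4% of those tested, and 53.6% of the calls were higher. Pseudogenes were 152 of the genes that rose and 528 of those that fell. The share higher was 52.4% after scaling by size factors and 43.6% after quantile normalization. At least a 2-fold change was also reached by 603 of the genes that rose and 139 of those that fell. Groups did not overlap for 8028 genes (43.6%), against 10% by chance. Knockout replicate 3 lay closer to the controls than the others, with 510 genes at least 2-fold from the control mean, against 1620 and 1801 in replicates 1 and 2. The total of 4298 genes became 5940 without it, 1875 without knockout replicate 1, 1604 without knockout replicate 2, 1901 without control replicate 1 and 2712 without control replicate 3. Of the 12 largest rises 10, and of the 12 largest falls 7, stayed past the threshold in each left-out fit that tested them.

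In Huh7, 6 lists were lower and 2 were higher by camera. Ribosome biogenesis factors fell in 18 of 21 cases (21 adjusted over the list alone; median -0.67, adjusted p = 4.18e-10), among them the fibrillarin gene FBL (-0.76), RRS1 (-0.95) and NOP56, from 450 ± 41.1 to 234 ± 71.7 CPM. Proliferation genes fell in 17 of 28 cases (21 adjusted over the list alone; median -0.58, adjusted p = 7.48e-09), with the helicase gene MCM3 at -0.96, the mitotic kinase gene PLK1 at -0.80 and the survivin gene BIRC5 at -0.67. SMN complex and Sm proteins fell in 9 of 19 cases (11 adjusted over the list alone; median -0.46, adjusted p = 1.61e-06), with SNRPD2 from 177 ± 7.31 to 115 ± 7.03 CPM. Cholesterol synthesis (7 of 22 lower, 8 adjusted over the list alone; median -0.27) and fatty acid synthesis (7 of 14 lower, 8 adjusted over the list alone; median -0.50) each had adjusted p = 0.00349, and ACLY, which makes cytosolic acetyl-CoA, fell from 546 ± 26.2 to 359 ± 8.30 CPM. The list of unfolded protein and amino acid stress genes was lower as well (10 of 21 members fell, 1 rose and 10 fell adjusted over the list alone; median -0.46, adjusted p = 0.00349), and the members that fell included the amino acid metabolism genes PSAT1 (-0.98), SHMT2 (-1.01) and ASNS (-1.46). Epithelial genes rose in 8 of 19 cases (8 adjusted over the list alone; median 0.97, adjusted p = 0.00398), with the adhesion gene EPCAM from 33.8 ± 12.8 to 113 ± 42.4 CPM and the tight junction gene CLDN3 from 0.432 ± 0.0146 to 5.80 ± 3.58 CPM. Cholangiocyte markers rose in 3 of 9 cases (4 adjusted over the list alone; median 0.73, adjusted p = 0.0146), and EPCAM belongs to both lists. The epithelial median stood at 0.61 in control replicate 2, above 0.32 in knockout replicate 3, and the cholangiocyte median at 0.36 and 0.49 in these libraries. A control is set here against the mean of the other controls and a knockout against that of all controls, so control values come out larger in size. None of the 8 calls held with an estimated correlation, where 0.457 was the lowest adjusted p. The call for cholesterol synthesis in Huh7 ended without knockout replicate 3 (adjusted p = 0.0682; up to 0.457 over the alternatives), and with quantile normalization, as did that for the stress list (adjusted p = 0.0569 for both).

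The other lists were not called in Huh7. Hepatocyte function genes had 3 of 32 higher and 1 lower (3 and 0 adjusted over the list alone; median 0.45, adjusted p = 0.128), and the risers were the fibrinogen genes FGG, from 202 ± 68.9 to 723 ± 91.1 CPM, and FGA, and the transcription factor gene FOXA1, from 89.1 ± 6.28 to 260 ± 79.2 CPM. With regional medians removed, the rise of FGG in Huh7 became 1.32 (adjusted p = 0.0104) instead of 1.89, and that of FGA in Huh7 1.29 (adjusted p = 0.027) instead of 1.87. YAP targets had 3 of 13 lower (median -0.67, adjusted p = 0.0996), hypoxia and glycolysis 1 of 18 higher and 5 lower (1 and 6 adjusted over the list alone; adjusted p = 0.127), and the interferon response 3 of 15 higher and 1 lower (adjusted p = 0.128), with the antiviral genes MX1 at 1.06 and OAS3 at 2.73. The p53 targets had 5 of 22 higher and 2 lower (adjusted p = 0.694), including SESN1 (1.20) and BTG2 (0.80). TGF-β receptors and SMADs had 2 of 20 higher (1 adjusted over the list alone; adjusted p = 0.356), with the ubiquitin ligase gene SMURF2 at 0.86. TGF-β target genes had 1 of 18 higher and 1 lower (0 adjusted over the list alone; adjusted p = 0.587). Mesenchymal genes had 2 of 14 higher and 1 lower, with a median of -0.01 and a mean of -0.10 while camera pointed up (adjusted p = 0.875), and the risers were the N-cadherin gene CDH2 (0.79) and the fibrillin gene FBN1 (1.37). The camera result was adjusted p = 0.223 for Wnt feedback and pan-tissue targets, 0.722 for perivenous liver genes and for fetal liver and progenitor genes, 0.128 for Wnt pathway components, 0.717 for NF-kB and inflammatory genes, 0.963 for stromal markers, 0.569 for endothelial markers and 0.51 for leukocyte markers. The stromal list had a median of -0.01, a mean of 0.07 and a camera result pointing down.

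None of the Wnt genes named in advance passed the threshold in both lines. Mean levels of CTNNB1, MYC and LGR5 were lower in the knockouts of both lines. On average over both lines, 3 of CTNNB1, AXIN2, LGR5, MYC and CCND1 passed. Of these, 2 kept the call in each left-out fit, and 1 in each other alternative too. CTNNB1, the β-catenin gene (chromosome 3, 41194837 to 41260096), fell in Huh6 from 561 ± 37.3 to 442 ± 35.3 CPM (log2 change -0.34, SE 0.10, adjusted p = 0.021), and stood at 679 ± 49.7 and 661 ± 42.9 CPM in Huh7 (adjusted p = 0.818). MYC fell in Huh7 from 58.9 ± 8.82 to 24.8 ± 11.3 CPM (log2 change -1.29, SE 0.28, adjusted p = 0.0109), and stood at 189 ± 5.87 and 131 ± 45.5 CPM in Huh6 (adjusted p = 0.142). LGR5, a receptor of R-spondins and a Wnt target, fell in Huh7 from 18.8 ± 3.61 to 4.52 ± 5.65 CPM (log2 change -2.33, SE 0.52, adjusted p = 0.012), and stood at 99.2 ± 5.95 and 81.4 ± 7.90 CPM in Huh6 (adjusted p = 0.72). AXIN2, a feedback inhibitor and standard Wnt target, stood at 106 ± 12.6 and 107 ± 11.9 CPM in Huh6 (adjusted p = 0.972) and at 5.33 ± 0.784 and 3.13 ± 2.59 CPM in Huh7 (adjusted p = 0.1). CCND1, the cyclin D1 gene, did not pass in either line (adjusted p = 0.206 in Huh6 and 0.611 in Huh7). The differences between the lines did not pass for CTNNB1 (adjusted p = 0.171), MYC (0.276) or LGR5 (0.105).

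In the list of Wnt feedback and pan-tissue targets, 4 of 21 members rose and 2 fell in Huh6, and 2 rose and 3 fell in Huh7. In Huh6 the transcription factor gene LEF1 rose from 0.431 ± 0.238 to 7.43 ± 2.39 CPM and the Wnt inhibitor gene APCDD1 from 32.9 ± 2.84 to 70.5 ± 11.3 CPM, and TCF7, another transcription factor of the pathway, from 93.9 ± 2.82 to 127 ± 6.13 CPM. In Huh7 the ephrin receptor gene EPHB2 rose from 20.9 ± 7.77 to 53.9 ± 8.25 CPM. The call for CTNNB1 in Huh6 was lost without control replicate 2 (adjusted p = 0.0919), control replicate 3 (0.0503) or knockout replicate 3 (0.0703), and in 3 other alternatives, with adjusted p up to 0.0818. The call for MYC in Huh7 was lost without knockout replicate 2 (adjusted p = 0.052), and that for LGR5 in Huh7 without knockout replicate 1 (adjusted p = 0.0525) and in 3 other alternatives, with adjusted p up to 0.0591.

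**Figure D2:**
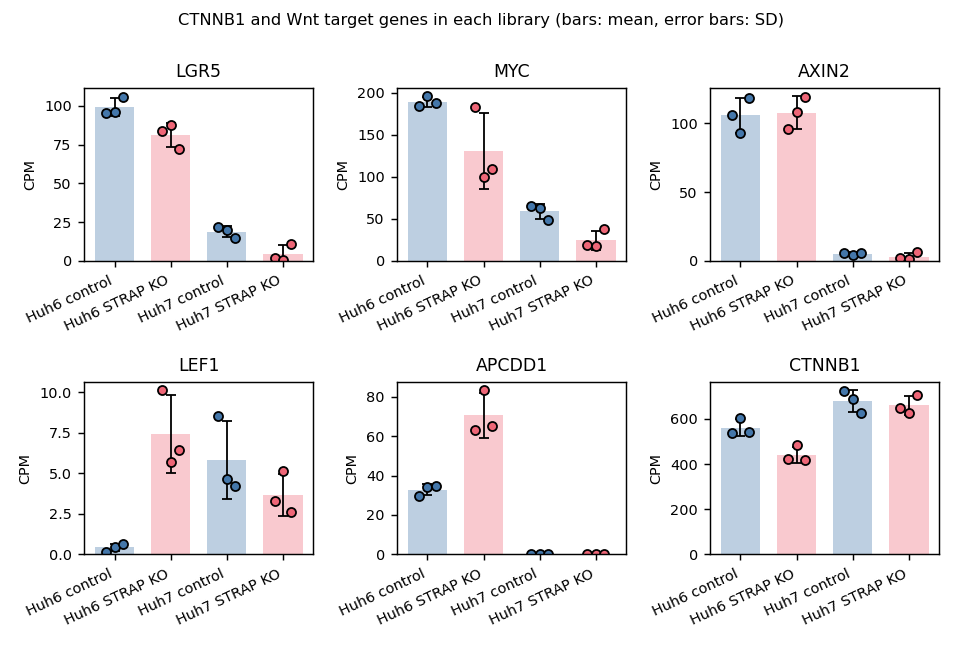
Level in CPM (y axes, one panel per gene) of LGR5, MYC, AXIN2, LEF1, APCDD1 and CTNNB1 in each library, as points, with the mean of the 3 libraries of a group as a bar and the SD as the error bar. MYC fell from 58.9 to 24.8 CPM in Huh7, LEF1 rose from 0.431 to 7.43 CPM in Huh6, and AXIN2 stood at 106 and 107 CPM in Huh6.

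The average change over both lines is the mean of the 2 changes, and a gene that changed in 1 line alone can pass it. The largest shared changes were therefore taken from genes called in both lines in the same direction. TXNIP, an inhibitor of thioredoxin that is induced by glucose (chromosome 1, 145992435 to 145996600), rose in Huh6 from 3 ± 1.19 to 31.2 ± 27.7 CPM and in Huh7 from 12.2 ± 5.76 to 89.3 ± 51.3 CPM (average log2 change 2.72, adjusted p = 0.00117). The p53 target gene TP53INP1 rose in Huh6 from 7.01 ± 0.398 to 33.1 ± 14.5 CPM and in Huh7 from 6.19 ± 2.79 to 27.9 ± 3.74 CPM, and CCNG2, a cyclin gene linked to cell cycle arrest, rose from 1.44 ± 0.128 to 12.7 ± 6.38 CPM and from 13.0 ± 0.384 to 57.4 ± 24.7 CPM. WNT5B, SEZ6L2, SBK1 and the glycosyltransferase genes GCNT1 and B3GNT7 also rose in both lines. DCDC2, a doublecortin domain gene of cilia (chromosome 6, 24171756 to 24358052), fell in Huh6 from 148 ± 8.53 to 26.9 ± 4.47 CPM and in Huh7 from 11.6 ± 3.96 to 2.02 ± 0.239 CPM (average log2 change -2.21, adjusted p = 3.27e-05). The ephrin receptor gene EPHA2, the biliverdin reductase gene BLVRB and the cold shock protein gene YBX3 fell in both lines as well. The average change of each of the 10 largest shared rises and 10 largest shared falls stayed past the threshold whichever library was left out, and their calls in single lines were not each retested. LOXL1-AS1 was among the 10 largest shared rises, and its overlap with LOXL1 leaves its own level uncertain.

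On average over both lines, 4417 genes rose and 2968 fell (40.1% of those tested), with at least a 2-fold change for 495 and 62 of them. Pseudogenes were 367 of the genes that rose and 891 of those that fell. Where reads were counted at more than one locus, a pseudogene can repeat the change of its parent gene. The share of calls that were higher was 59.8%, and 49.6% with size factors or 43.1% with quantile normalization. Ribosome biogenesis factors fell in 21 of 21 cases (median -0.58, adjusted p = 2.61e-10), proliferation genes in 24 of 28 (adjusted p = 5.23e-09), SMN complex and Sm proteins in 12 of 19 (15 adjusted over the list alone; adjusted p = 8.56e-07) and cholesterol synthesis genes in 11 of 22 (adjusted p = 0.00135). Fatty acid synthesis genes fell in 6 of 14 cases and rose in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.011). Wnt pathway components rose in 13 of 30 cases and fell in 1 (adjusted p = 0.0302). With an estimated correlation none of the 6 lists was called, the lowest result being adjusted p = 0.439. Of 14 other alternatives 6 ended the call for Wnt pathway components and 2 that for fatty acid synthesis.

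**Figure D3:**
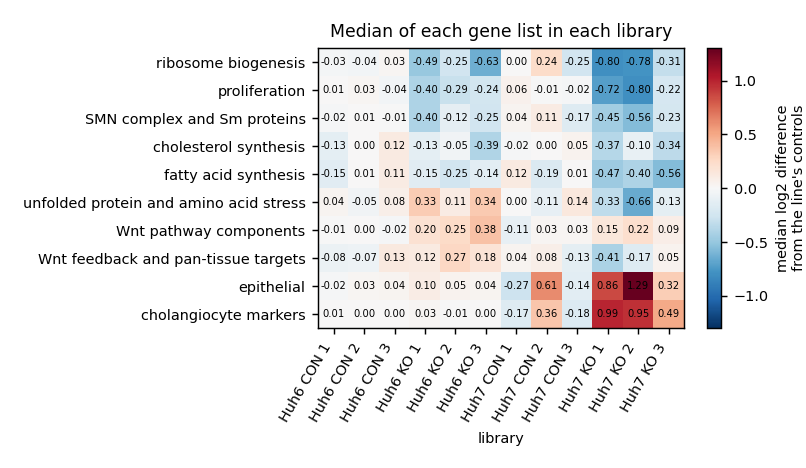
Median log2 difference of 10 gene lists (rows of the grid) from the controls of the line, in each of the 12 libraries (columns). The value is printed in each cell and coloured red above 0 and blue below 0. A knockout is set against the mean of all controls and a control against the mean of the others, which makes control values larger in size. Ribosome biogenesis lies between -0.80 and -0.25 in the 6 knockout libraries. In Huh7, control replicate 3 stands at -0.25 and knockout replicate 3 at -0.31, on these unlike scales. The cholangiocyte list lies at 0.99, 0.95 and 0.49 in the Huh7 knockouts.

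The lines shared more calls than independent lists would. Of the genes called, 908 were higher in both lines, against 447.5 expected from lists drawn independently, and 557 were lower in both, against 209.8 (Fisher's exact p = 2.31e-127 and 2.11e-121 across genes, which are not independent replicates). A further 99 were higher in Huh6 and lower in Huh7 (387.3 expected), and 40 the other way (242.5 expected). Pseudogenes among the shared genes were not counted apart, and copies that share reads with a parent gene can repeat its call. Whether shared rises outnumber shared falls turns over with the scaling: 712 were higher and 756 lower in both lines with size factors, and 603 and 832 with quantile normalization. The lines have separate controls. Across genes, the changes in the lines had Pearson's r = 0.317 and Spearman's rho = 0.405. With group labels exchanged within lines in 100 regroupings, r ranged from -0.345 to 0.345, and 2 were at least as large in size as the real r and 2 as the real rho (permutation p = 0.0297 for each). The 1465 genes shared in the same direction became 830, 803 and 774 without Huh6 control replicates 1, 2 and 3, 720 without Huh7 control replicate 1, and 779 and 678 without Huh7 knockout replicates 1 and 2.

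**Figure D4:**
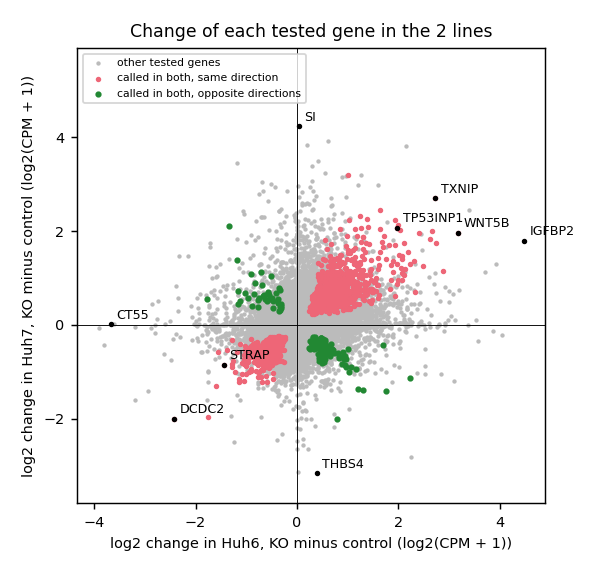
Log2 change of each of the 18396 tested genes in Huh6 (x axis) and in Huh7 (y axis), knockout minus control on the log2(CPM + 1) scale, with genes called in both lines coloured by whether the directions match. The match is in the same direction for 1465 genes, a total that stood at 1468 with size factors and 1435 with quantile normalization, and in opposite directions for 99 and 40.

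Some genes responded differently in the 2 lines, by a test of the difference itself. TIMP3 rose in Huh6 and stood at 82.1 ± 1.86 and 76.5 ± 22 CPM in Huh7 (difference 4.01, Huh6 minus Huh7, adjusted p = 0.000522). THBS4, which fell in Huh7, stood at 0.332 ± 0.0418 and 0.753 ± 0.257 CPM in Huh6 (difference 3.54, adjusted p = 0.0035). The adhesion gene NECTIN1 rose in Huh6 from 3.35 ± 0.709 to 25.4 ± 9.45 CPM and stood at 31.7 ± 6.09 and 17.7 ± 8.30 CPM in Huh7 (difference 3.41, adjusted p = 0.00357). LITAF, an endosomal protein gene, fell in Huh6 from 188 ± 18.0 to 41.8 ± 27.7 CPM and stood at 4.96 ± 2.90 and 14.4 ± 5.55 CPM in Huh7 (difference -3.79, adjusted p = 0.0111). CT55 was below 0.2 CPM in each Huh7 group, so its difference rests on Huh6 alone. In all, 1088 genes had a more positive and 655 a more negative change in Huh6 than in Huh7 (1743 genes, 9.5% of those tested; 62.4% positive, and 46.2% with size factors or 52.1% with quantile normalization), of which 446 and 309 differed by at least 2-fold.

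The stress list differed between the lines (10 of 21 more positive in Huh6 and 1 more negative, 14 and 1 adjusted over the list alone; median difference 0.88, adjusted p = 8.05e-05), with the chaperone gene CALR at 0.88 (adjusted p = 0.00621). Epithelial genes (0 more positive and 1 more negative of 19; median difference -0.81, adjusted p = 0.00401) and cholangiocyte markers (1 more negative of 9, 4 adjusted over the list alone; median difference -1.05, adjusted p = 0.00409) were more positive in Huh7. With an estimated correlation the lowest result for the 3 lists was adjusted p = 0.716. Of 14 other alternatives 5 ended the call for cholangiocyte markers and 2 that for epithelial genes. The Wnt feedback list did not differ past the threshold (adjusted p = 0.217). The count of 1743 genes was the least stable, and became 726, 485 and 548 without Huh6 control replicates 1, 2 and 3, 687, 1136 and 948 without Huh7 control replicates 1, 2 and 3, and 786 and 794 without Huh7 knockout replicates 1 and 2. It became 3404 without Huh6 knockout replicate 1 and 3327 without Huh7 knockout replicate 3.

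The control cultures of the lines differed widely, which gives the background for the knockouts. The glucose transporter gene SLC2A3 stood at 5168 ± 665 CPM in the Huh6 controls and 3.98 ± 2.09 CPM in the Huh7 controls (log2 difference 10.09, adjusted p = 1.37e-08). The laminin gene LAMA1 (1016 ± 128 against 0.196 ± 0.153 CPM) and the keratin gene KRT19 (564 ± 40.7 against 0.340 ± 0.203 CPM) were higher in Huh6. The growth factor gene IGF2 (0.430 ± 0.283 against 1640 ± 598 CPM), the albumin gene ALB (22.4 ± 7.84 against 17048 ± 2884 CPM) and the RNA-binding protein gene LIN28B were higher in Huh7. Wnt feedback and pan-tissue targets were higher in Huh6 in 15 of 21 cases and lower in 2 (median 2.20, adjusted p = 0.00785), with SP5 at 196 ± 16.2 against 8.46 ± 1.86 CPM. The p53 targets were higher in Huh6 in 20 of 22 cases (median 2.33, adjusted p = 9.42e-08), with MDM2 at 373 ± 16.3 against 56.2 ± 0.576 CPM, and epithelial genes in 16 of 19 (median 1.82, adjusted p = 0.00995). None of these 3 calls held with an estimated correlation, where the lowest result was adjusted p = 0.402. Altogether 6233 genes were higher in Huh6 and 6036 higher in Huh7 (66.7% of those tested), 2721 and 2805 of them by at least 2-fold.

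Genes of some chromosome regions shifted together in the knockout libraries, and these shifts run beside the changes above. A knockout was set against the mean of all controls of its line and a control against the mean of the others. That makes the shifts of controls larger in size than on the knockout scale. On chromosome 22 the median log2 difference from the Huh7 controls over 256 protein-coding genes was -0.56 in knockout replicate 1, -0.46 in replicate 2 and -0.04 in replicate 3, and 102 genes of the chromosome were lower and 29 higher in Huh7 out of 453 tested. In Huh6, 25 of them were lower and 101 higher. Regions of 20 Mb whose median lay at least 0.3 from the controls in the same direction in each of the 3 knockouts were, in Huh6, chromosome 3 from 100 to 120 Mb (0.37 to 0.52), chromosome 9 from 20 to 40 Mb (-0.78 to -0.62), chromosome 12 from 80 to 100 Mb (-0.53 to -0.42) and chromosome 13 from 100 to 120 Mb (0.39 to 0.57). In Huh7, chromosome 4 from 140 to 160 Mb stood at 0.47 to 0.71 in the knockouts, but also at 0.44 and 0.42 in control replicates 1 and 3, with control replicate 2 at -0.86. Of 149 regions, 28, 21 and 17 lay that far off in the 3 Huh6 knockouts and 0 in each Huh6 control. The count was 16, 5 and 3 in the Huh7 knockouts and 5, 6 and 5 in the Huh7 controls, where the wider scale of controls can raise it.

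**Figure D5:**
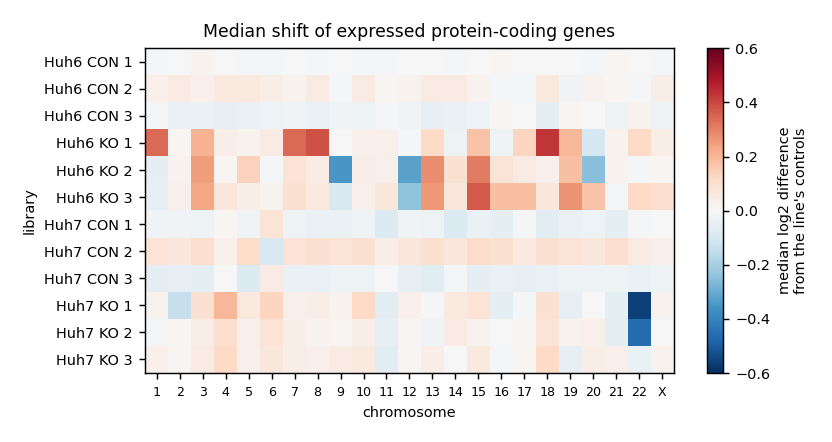
Median log2 difference of expressed protein-coding genes from the controls of the line, for each chromosome (x axis) in each library (y axis), coloured red above 0 and blue below 0. A knockout is set against the mean of all controls and a control against the mean of the others, which makes control values larger in size. Chromosome 22 stands at -0.56 and -0.46 in Huh7 knockout replicates 1 and 2 and at -0.04 in replicate 3.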

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

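Chosen only after the result was seen were the tests of random clustering and of a shared response for chromosome 22, of STRAP mRNA for Huh7 knockout replicate 3, of loss of STRAP for the growth lists, and the splits within Huh6 and within Huh7. The other tests were set before their results were seen.

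What brought the results of this part forward is a difference between Huh6 and Huh7 in the change with STRAP targeted, tested as an interaction. Of 213 genes named in the text or its tables, 76 differed, 48 of them with changes of opposite sign. The 213 include genes that the rule named because this same test passed, so 76 of 213 is not a rate. Over all tested genes 9.5% differed. Called in Huh6 alone were 37 genes, in Huh7 alone 31, and in both lines in opposite directions 4. For 3 of these 4 the call in Huh7 was lost in several of the 12 fits with a library left out: 8 for FOXA2, 5 for CD14 and 4 for FJX1. The call for FJX1 in Huh6 was lost in 5. The call for the difference was retested only for genes that the rule named for it. These were 8 in each direction and 41 list members, with overlap. It held for 22 of them in each left-out fit that tested the gene, and for 16 of these in each other alternative that refitted it too. It was lost in up to 10 of the left-out fits. CT55 reached 1 CPM in the Huh6 controls alone, so it was not tested when a Huh6 control was left out. Values are log2 differences, the change in Huh6 minus that in Huh7, and genes near 0 CPM in one line differ through the other line alone.

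Among the largest by change in 1 line, MAP1B stood at 4.28, ALCAM at 4.27, TIMP3 at 4.01, DOC2B at 3.89, THBS4 at 3.54, MARK1 at 3.42, NECTIN1 at 3.41, CSF3R at 3.4, SCN4A at 3.37, GC at 3.15, SLC47A1 at 3, NDRG4 at 2.92, NUPR1 at 2.81, SLC7A1 at 2.28, TENM2 at 2.27, PLA2G4A at 2.08 and RASSF9 at 2.03. On the negative side were SI at -4.21, NAV3 at -3.84, LITAF at -3.79, CES1 at -3.74, CT55 at -3.69, NEBL at -3.63, GUCY1A2 at -3.54, RAP1GAP2 at -3.53, OLR1 at -3.4, SLC2A2 at -3.32, ODAM at -3.3, GPRC5A at -2.89, KIF17 at -2.81, ZNF804A at -2.81 and TMEM178B at -2.19. CES1 shares reads with a pseudogene, so its value is uncertain.

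Wnt genes that differed were LEF1 (3.06), FZD4 (1.37), SLCO1B3 (1.23), BCL9 (1.2), FZD1 (1.02), APCDD1 (1) and DVL3 (0.71). The sign turned for APCDD1 in interaction with edgeR (-0.50) and DESeq2 (-0.51), and for SLCO1B3 in interaction with edgeR (-0.39). TGF-β genes that differed, besides TIMP3, were BHLHE40 (1.66), ACVR2B (1.01) and NEDD9 (-2.14). Liver and progenitor genes were H19 (2.12), PEG3 (1.29), FOXA2 (1.26), ASGR2 (0.62), FOXA1 (-1.17) and EPCAM (-1.77), and mesenchymal genes CDH2 (-0.84) and FBN1 (-1.51). Stress and amino acid genes were ASNS (1.66), CHAC1 (1.2), PSAT1 (1.11), SHMT2 (1.01), PDIA4 (1), HSPA5 (0.93) and CALR (0.88). Genes of growth and metabolism were ELOVL6 (1.01), MCM3 (0.96), RRS1 (0.85), HK2 (0.73), FASN (0.72), BIRC5 (0.64), GPI (0.6) and SNRPD2 (0.5), and of p53 and inflammation BBC3 (0.97), TNFRSF10B (0.7), XPC (-1) and TNFAIP3 (-2.05). FJX1 (2.56), TIE1 (1.66), CD14 (1.58), IFIT1 (1.17), ENG (0.96) and MX2 (0.67) differed as well. Of the lists, the stress list had a median difference of 0.88, the epithelial list -0.81 and the cholangiocyte list -1.05, and over the tested genes 1743 differed. None of these list calls held in camera with an estimated correlation (adjusted p = 0.716 for each), and 5 of 14 other alternatives ended that for cholangiocyte markers.

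Chromosome 22 genes were lower in Huh7 knockout replicates 1 and 2, with medians of -0.56 and -0.46. Of 10000 random gene sets of the same size 0 had a median as far from 0, against random clustering of changed genes, and the 86 most expressed genes still had a median of -0.56 in the library nearer 0, against noise of lowly expressed genes. A response shared by each STRAP knockout culture is argued against by replicate 3, where the median was -0.04 with a 95% bootstrap interval from -0.083 to 0.015. A lower copy number of the chromosome in these 2 cultures stays open, because the share of genes below 0 in a 10 Mb window was at least 74.4%, short of the 75% set beforehand for it and above the 60% set against it. No DNA was measured.

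Huh7 knockout replicate 3 lay closer to the controls than replicates 1 and 2, with a root mean square log2 distance of 0.408 against 0.625 and 0.666. More STRAP mRNA left in replicate 3 is argued against, since replicate 2 had 127.6 CPM of STRAP and replicate 3 had 125.1 CPM, while their distances differed by 0.258. Control cells mixed into the culture of replicate 3 stay open as a hypothesis, which predicts few genes changed in replicate 3 alone. In it 85 genes lay over 2-fold from each control, and did so in neither other knockout. A control left out gave 29 to 129 genes, but against the other controls only and with no genes of the knockouts removed. The counts are therefore unlike, and their comparison cannot decide. Control cells mixed with cells like replicates 1 and 2 would not account for all of replicate 3, where the median of TGF-β receptors and SMADs was 0.51, against at most 0.17 in the other Huh7 libraries, and that of NF-kB and inflammatory genes 1.39, against at most 0.97. A clone with a milder response to the same targeting could give the same count of 85 and was not tested apart from it.

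Ribosome biogenesis, proliferation and SMN lists were lower in both lines, calls that were lost with an estimated correlation (lowest adjusted p = 0.736 in Huh6 and 0.457 in Huh7). The fry test also ended that for proliferation in Huh6 (adjusted p = 0.0961). In Huh7, control replicate 3 stood at -0.25 and knockout replicate 3 at -0.31 for ribosome biogenesis, and at -0.17 and -0.23 for the SMN list. The control is set against the mean of the other controls, which makes its values larger in size than on the knockout scale. After the median of each 20 Mb region was removed, 3 of the 3 lists kept at least 70% of their median change in both lines, against regional shifts of chromosomes as the cause, and 3 of the 3 did so with either scaling, against the scaling of the libraries. Of the 18 medians of these lists in the knockout libraries, 18 lay below 0, but the lists were picked because they were lower, so this count tells nothing for or against loss of STRAP. Loss of STRAP, differences between sorted clones and the time in culture that sorting takes all stay open, because the design has no STRAP re-expression. RNA quality or selection was not tested and stays open in Huh6, where the share of mitochondrial genes did not overlap between the groups. The share matched as histones did not overlap either, but it includes H19, which rose in Huh6, so it cannot be read for histones alone.

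Splits of the libraries show how often other groupings give as many calls. For each of the contrasts of 3 against 3 libraries, 10 splits are too few for a share under 0.05: 1 gave as many calls, the real one, with 5509 genes in Huh6 (highest other 0), 4298 in Huh7 (highest other 4) and 12269 between the controls (highest other 0). On average over both lines 1 of 100 splits gave as many calls, the real one with 7385 genes (highest other 1743), so a chance split of the libraries can be excluded at that share. For the difference between lines 3 of 100 splits gave as many as the real 1743 genes, and the highest other gave 7385. That split exchanges the labels of 1 line, which turns the difference into the average, and points to a change shared by the lines; the highest apart from it was 2394. These splits also take away the change within each line, so they test for no change at all, and chance is not excluded for the difference between lines alone. For gene lists on average over both lines, 58 of 100 splits gave at least the real 6 calls (highest other 12), so the number of lists called can arise from chance splits and the lists rest on their values in each library.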

How the results depend on the processing

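The fits of protein-coding genes alone and with regional medians removed were chosen after seeing the data. The p-values measure the spread between these libraries, pooled over the 4 groups although knockouts varied more than controls. No alternative can separate STRAP from differences between clones. Through the pooling, the Huh7 count became 5753 without Huh6 knockout replicate 1. With each line fitted alone, 4269 genes were called in Huh6 and 3509 in Huh7, and 1000 were shared in the same direction. STRAP then had adjusted p = 0.00508 in Huh6 and 0.0298 in Huh7. Depth limits genes below about 0.0264 to 0.0401 CPM, and the count tools rest on recovered counts. STRAP stayed past the threshold in each line in each alternative that refitted it, from -1.56 to -1.21 in Huh6 and from -0.96 to -0.64 in Huh7, but at 1.77-fold in Huh7 it falls short of a 2-fold minimum. No paired analysis was possible because the replicate numbers were given here in accession order and the labels share none between groups.

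Without a filter on low values, 943 genes were shared between the lines in the same direction, against 1465. With array weights the counts became 9096 in Huh7, 5484 for the difference between lines and 3216 shared, and DESeq2 gave 2790 for that difference. With an estimated correlation camera called 0 lists in either line, against 13 with its preset, 3 higher and 10 lower; 1 list in each line had an unadjusted p under 0.05, and fry called 6 in Huh6 and 10 in Huh7. In Huh6 fry ended the calls for proliferation and cholesterol synthesis and added both TGF-β lists and endothelial markers. In Huh7 fry kept each camera call and added 2 lists. These were Wnt pathway components, higher (fry adjusted p = 0.00851), and hypoxia and glycolysis, lower (0.0317). With a 2-fold minimum the counts were 1077 in Huh6, 742 in Huh7, 557 on average, 755 for the difference and 5526 between controls. With 1 library left out the counts ranged from 3154 (without Huh6 control replicate 2) to 6245 (without Huh7 knockout replicate 3) in Huh6 and from 1604 (without Huh7 knockout replicate 2) to 5940 (without Huh7 knockout replicate 3) in Huh7. They ranged from 5781 to 8341 on average, from 485 (without Huh6 control replicate 2) to 3404 (without Huh6 knockout replicate 1) for the difference, from 10970 to 12952 between controls, and from 678 (without Huh7 knockout replicate 2) to 2128 (without Huh7 knockout replicate 3) for shared genes. The correlation between lines ranged from 0.256 to 0.351, and the list calls from 12 to 14. The list calls were 7 higher and 7 lower with quantile normalization, and 5 and 9 with each line fitted alone. Limma, edgeR and DESeq2 together called 4659 genes in the same direction in Huh6, 3715 in Huh7 and 1093 for the difference.

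The sign turned for CHAC1 on average with edgeR (0.22), for APCDD1 in the difference with edgeR (-0.50) and DESeq2 (-0.51), for SLCO1B3 in the difference with edgeR (-0.39), and for SNRPF in Huh6 with regional medians removed (0.03). CHAC1, APCDD1 and SLCO1B3 are near 0 CPM in 1 line, and the cause was not tested for these or for the other moves. Protein-coding genes alone gave 4117 calls in Huh6 and 3246 in Huh7, and regional medians removed gave 5539 and 4421. TGF-β receptors and SMADs in Huh6, not called above, passed with no filter (adjusted p = 0.0144) and with quantile normalization (0.0264), and the interferon response in Huh7 with edgeR (0.0178) and DESeq2 (0.00403).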

Other observations

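These values were picked out after the tables had been seen, from genes named by the rule set before. The hypoxia and glycolysis list was not called in either line, and a member of it is given here because of its size. ENO1, the enolase gene, fell in Huh6 from 2025 ± 132 to 1021 ± 186 CPM (log2 change -1, adjusted p = 0.00217, n = 3) and in Huh7 from 1691 ± 117 to 932 ± 219 CPM (-0.88, adjusted p = 0.0069).

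The fibrinogen chain gene FGG had a higher mean in the knockouts of both lines, from 455 ± 106 to 937 ± 375 CPM in Huh6 (log2 change 0.99, adjusted p = 0.0404) and from 202 ± 68.9 to 723 ± 91.1 CPM in Huh7 (1.89, adjusted p = 0.00399). FGA went from 269 ± 43.0 to 660 ± 424 CPM in Huh6, where it did not pass (adjusted p = 0.0501), and from 293 ± 103 to 1029 ± 178 CPM in Huh7. Both lie on chromosome 4 in a region of 20 Mb where Huh7 control replicate 2 stood at -0.86 from the other controls. With regional medians removed FGG in Huh7 stood at 1.32 (adjusted p = 0.0104) and FGA in Huh7 at 1.29 (adjusted p = 0.027). The imprinted genes H19 and PEG3 rose in Huh6, PEG3 from 182 ± 11 to 468 ± 166 CPM (adjusted p = 0.00223), and were below 1 CPM in each Huh7 group. No test of a shared regulator of these genes was made.

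Knockout libraries varied more than controls. The median SD of a gene on the log2 scale was 0.219 in the Huh6 knockouts and 0.075 in the Huh6 controls, and 0.164 and 0.119 in the Huh7 groups. Among whole chromosomes, chromosomes 1, 7, 8 and 18 stood higher in Huh6 knockout replicate 1 alone, and chromosome 9 stood lower in Huh6 knockout replicate 2. Others shifted in more than 1 culture. Chromosome 12, which carries STRAP, had medians of -0.01, -0.32 and -0.24 in Huh6 knockout replicates 1, 2 and 3. Chromosome 15 stood at 0.17, 0.31 and 0.37 in these libraries, and chromosome 3 at 0.21, 0.25 and 0.23.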
